A study of Homo sapiens and synthetic construct with 19 samples.

How the data were processed

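A massively parallel reporter assay was used, in which many short DNA elements are placed in reporter constructs that each carry a DNA barcode, so that the RNA reads of a barcode, set against its abundance in the plasmid pool, give the activity of the element it marks. The library held 9719 elements marked by 91966 barcodes, with a median of 10 barcodes per element. Of these, 9558 were elements of 135 bp that each carried a pair of transcription factor motifs, and 89 negative and 72 positive controls of 136 bp completed the set. The 2-motif elements came from 239 motif pairs with 10 parent sequences each, and 2388 of the 2390 parent sequences were present in all 4 versions: unmutated, the left motif scrambled, the right motif scrambled, and both scrambled. Version codes scrA and scrB marked the left and the right scrambled stretch in all 2390 parent sequences, whatever the order of the motif names. The stretches never overlapped, and the changed span had a median of 19 bp and at most 22 bp. Each pair carried 1 of 6 tags (Colon, GDSD6, GM12878, MM, Melanocytes or SCC), which are used as they stand.

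The deposited values are raw read counts per barcode for each library, and the authors' matrix over the RNA libraries holds the same counts in all 1655388 cells that could be compared, with 0 that differ. One column of that matrix, 1 in all, was not used. Per the labels' protocols, total RNA was purified with RNeasy columns and 3' end libraries were made with a Lexogen QuantSeq kit from oligo-dT priming, then sequenced as single-end reads on an Illumina HiSeq instrument. Per the submitters' processing notes, Bowtie2, DESeq2 and the build hg19 were named, without roles. The counting rule and the tool versions were not given in the sources used here. No molecular identifier was named, so PCR copies were counted as reads, and every interval below covers counting or sampling error of these values only. Genomic positions of the elements were not used here.

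Groups were taken from the labels: colonic epithelial cells, the lymphoblastoid line GM12878, keratinocytes differentiated for 6 days in 1.2 mM calcium, melanocytes, the melanoma line COLO 829 and the epidermoid carcinoma line A-431, with 3 libraries each, and 1 plasmid library. The COLO 829 libraries carried DMSO labels of 1, 2 and 2 µM for replicates 1, 2 and 3, at 24 hours, while melanocytes were labelled untreated. Replicates are named as biological by the series, but nothing ties them to separate donors, so edgeR p-values measure the spread between these libraries. The sign-flip and permutation tests below use 1 value per sequence and cell type, so their p-values measure the spread between sequences. The test over barcodes averages the libraries and measures the spread between barcodes. A chi-square test over barcodes with at least 20 reads in a pair was run before any comparison was fitted. Replicates 2 and 3 of A-431 differed by less than sampling noise (chi-square per degree of freedom of 0.93 over 44220 barcodes, p = 1, against 1.58 and 1.85 for the other 2 pairs). They were summed and counted as 1 sample, so A-431 has n = 2. Replicates 1 and 3 of COLO 829 were close to that noise (chi-square test, 1.07 per degree of freedom over 72469 barcodes, p = 4.3e-39) and were kept apart.

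Total counts ran from 1958642 reads (GM12878 replicate 3) to 24934540 reads (COLO 829 replicate 1) in RNA and were 27452943 in the plasmid library. The median element had 78 reads in GM12878 replicate 3 and 1002 in COLO 829 replicate 1. Between 78.2% and 95.3% of barcodes were detected in an RNA library, and 97.8% in the plasmid library. Elements with under 50 plasmid reads (425) were left out of the edgeR fits, which left 9294. The test of controls and the first correlations between libraries in the results were run without this minimum.

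Reads were summed over the barcodes of an element, and levels of single elements are given as CPM, reads scaled to a common library size. These levels are not divided by plasmid reads. Where a cell type was set against several others, the SD of the others holds differences between cell types as well as between replicates. Cell types were compared with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10, glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment at 0.05) in 1 fit over all RNA libraries. The plasmid abundance of an element was assumed to be the same in all cell types and so to cancel in these comparisons. It was not measured in the cells, since only the plasmid pool was sequenced. Effects of barcodes on RNA need not cancel. Elements differing by more than 2-fold were called with glmTreat. Activity was tested in a fit that added the plasmid library. An active element had an RNA to plasmid ratio above that of the typical element. The single plasmid library was assumed to vary like the RNA libraries. Motif lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, over unmutated elements and with a minimum of 5 elements. The lists covered factors of keratinocytes, AP-1, melanocytes, B cells, intestinal epithelium, broadly used promoter factors, TEAD, MYC, STAT, other lineages, and insulator or repressor factors. The AP-1 list held MAF factors and BACH1 beside FOS, JUN and BATF factors. An element belonged to each list that held 1 of its motifs. Copies of one sequence under several names counted as separate elements, so list members are not all distinct sequences. Results for a further item are not reported here. No motif name of the library was on the TEAD, MYC or other-lineage lists (0 members each), so these were not tested. Scrambled versions were compared within a library by edgeR with log plasmid reads as an offset.

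The 4 versions of a sequence carry different barcodes, and the spread between barcodes is not part of the spread between libraries. A first fit called most sequences changed by scrambling, so a moderated limma test over barcodes was added after that result was seen, for barcodes with at least 10 plasmid reads and versions with at least 3 such barcodes. A null comparison came from 399 unmutated sequences that were present under more than 1 name (868 elements), each copy with its own barcodes. Counts from the test over libraries remain the planned ones and stand beside those from the test over barcodes. Further tests were added after the data were seen, all 2-sided sign-flip permutation tests over distinct sequences (100000 resamples, exact up to 12 sequences): for sequences naming a motif, with both motifs scrambled; for sequences whose scrambled stretch lost 1 of 16 textbook consensus sites; and per pair. Stretches with a site were also compared with 2601 stretches that held none of the listed sites, in a permutation of the labels (100000 resamples, 84 tests). An earlier assignment of single scrambled stretches to motif names by name order was dropped, because the codes are positional. A first test of plasmid-derived reads in GM12878 used elements selected by their own fold change, which largely set the share it computed, and it was replaced by a limit from elements selected in the other cell types, after the values were seen. The correction for GC content (a smooth offset per library) was also added after the data were seen, as was the counting of 2 A-431 replicates as 1 sample and of COLO 829 replicates 1 and 3 as 1 sample in an alternative.

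The design, the lists, the alternatives to be tried and the choice of named items were made before the data were examined. For each comparison, the items eligible for naming were the 10 elements or parent sequences with the highest and the 10 with the lowest log2 fold change past the threshold with all replicates on one side, and the 5 highest and 5 lowest pairs by median. Of these, elements with a group near 0 reads were passed over in the text after their values were seen, since such fold changes depend on the prior count. Alternatives listed beforehand were DESeq2 1.42.0 size factors and its Wald test, limma on log2 ratios per library (pseudocount of 1 read) or on medians over barcodes, scaling to the negative controls or taking them as the zero of activity, no filter on low counts, no plasmid offset, plasmid minimums of 10 and 200 reads, a minimum change of 1 on the log2 scale, an estimated correlation, all versions in the lists, leaving out the top barcode of each element, a replicate block, only the compared cell types in the fit, and leaving out each library in turn. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for the rest.

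The programs were tested on simulated data. For COLO 829 against melanocytes over 9236 elements, 88 of 100 elements changed by 1.5-fold and 100 of 100 changed by 2-fold were recovered, with 7 false calls. For scrambling in GM12878 over 2179 sequences, 179 of 200 changed by 2-fold were recovered with 9 false calls. With no effect but barcode noise of 1 log2 SD per element, the same test over libraries called 1716 of 2188 sequences in GM12878. This noise was larger than that in the data, where the difference between 2 copies of one sequence had an SD of 0.732 in GM12878. Of those real pairs 53.9% were called. The test over barcodes was first simulated with 2-fold changes, of which it recovered few, and then with 4-fold ones. With 10 barcodes per version and a spread of 1 log2 SD, it recovered 17 of 200 sequences changed by 2-fold with 1 false call, and 191 of 200 changed by 4-fold with 16 false calls, over 2207 sequences each. For a 4-fold departure from additivity it recovered 120 of 200 with 5 false calls over 2207 sequences. It therefore misses most changes of 2-fold, and its counts are lower limits in that sense. The sign-flip test recovered 19 of 20 shifted sets and called 0 of the unshifted ones among 60 sets of 30 units.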

Results

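The activity of 9719 short DNA elements was measured with a barcoded reporter library in colonic epithelial cells, differentiated keratinocytes, melanocytes, the B-lymphoblastoid line GM12878, the melanoma line COLO 829 and the epidermoid carcinoma line A-431. Each cell type had 3 RNA libraries, and 1 library gave the plasmid pool. Replicates 2 and 3 of A-431 differed by less than the sampling noise and were counted as 1 sample, so n = 2 for A-431 and n = 3 elsewhere. Replicates 1 and 3 of COLO 829 were close to that noise (chi-square per degree of freedom of 1.07) and were kept as separate samples. Counting them as 1 sample left the COLO 829 counts within 1.5 times of the first value. RNA depth ran from 1958642 reads (GM12878 replicate 3) to 24934540 reads (COLO 829 replicate 1). The 3 GM12878 libraries were the shallowest on average, and calls there rest on fewer reads. The series asks how pairs of motifs act together in a cell type. Its design compares unmutated elements with versions whose left, right or both motifs were scrambled, and compares cell types with one another. Across elements, which are not replicates, log2 RNA over plasmid correlated at 0.97 to 0.98 (Pearson) between colonic libraries, 0.9 to 0.92 between GM12878 libraries and 0.98 to 0.99 between COLO 829 libraries. Between cell types the lowest value was 0.63, and libraries of GM12878 reached at most 0.8 with any other cell type.

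The share of elements called active was larger for unmutated elements than for those with both motifs scrambled, by the least in GM12878; this difference of shares was not tested, and the calls do not include the spread between barcodes. The RNA to plasmid ratio was above that of the typical element (edgeR, adjusted p under the threshold) for 42.8% of 2279 unmutated elements in colonic epithelial cells, 41.5% in keratinocytes, 39.3% in melanocytes, 40.9% in COLO 829, 40% in A-431 and 34.1% in GM12878. With both motifs scrambled the shares of 2276 elements were 29.8%, 29%, 30.1%, 29.8%, 29.3% and 31.9% in the same order. In all, 3338 of 9258 elements were active in colonic epithelial cells, 3238 in keratinocytes, 3184 in melanocytes, 3236 in COLO 829, 3169 in A-431 and 3031 in GM12878. Of the negative controls, 30.7% of 88 were active in colonic epithelial cells and 52.3% in GM12878, and the other cell types lay between. Since active means above the typical element, these shares cannot tell whether the negative controls were silent. No difference between positive and negative controls passed in a two-sided permutation test of 72 against 89 elements, with differences of -0.49 in GM12878 (permutation p = 0.0196, adjusted p = 0.118 over 6 tests) to 0.23 in colonic epithelial cells (adjusted p = 0.662). This test kept controls with few plasmid reads, while the calls of active elements covered 64 positive and 88 negative controls. Activity is by definition relative to the typical element of the library, not to a sequence known to be inactive.

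Melanoma cells were compared with melanocytes; the COLO 829 libraries were labelled with DMSO for 24 hours and the melanocytes as untreated, so cell type and treatment differed together. Elements with motifs of melanocyte factors were lower in COLO 829: of 179 elements naming SOX10, LEF1, MITF or TFE3, 67 fell and 10 rose, with a median log2 fold change of -0.14 (camera adjusted p = 1.54e-06; the median is -0.02 with scaling to the negative controls). Elements naming MITF, the master regulator of pigment cells, had a median of -0.21 with 9 of 19 lower and 0 higher, and those naming SOX10, a neural crest factor upstream of it, had -0.12 with 30 of 90 lower and 6 higher. LEF1 had -0.16 (24 lower, 2 higher) and TFE3, named only in pairs with KLF4, 0.02 (4 lower, 2 higher). Elements of AP-1 and related basic zipper factors went the other way, with 61 of 169 higher and 25 lower (median 0.14, camera adjusted p = 0.00465). Of single elements, JUN::SREBF2+GDSD6+2+scrA_B rose from 82.3 ± 13.9 CPM in melanocytes to 296 ± 8.24 (SD, n = 3 each; log2 fold change 1.85 ± 0.09 SE, edgeR adjusted p = 2.02e-13). IRX3::TP63+SCC+4+A_B fell from 495 ± 50.2 to 119 ± 2.24 (log2 fold change -2.05 ± 0.08 SE, edgeR adjusted p = 3.56e-15).

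In this comparison 3356 of 9258 elements differed by edgeR, 1712 higher and 1644 lower, and 31 differed by more than 2-fold (24 higher, 7 lower). Scaled to the negative controls, 2487 were higher and 901 lower, and the median of all elements moved from 0 to 0.12. Of the lists fixed beforehand, 7 of 8 passed. Besides those above, STAT motifs were lower (8 up, 49 down of 148, median -0.12, adjusted p = 5.41e-05; the median is 0 with scaling to the negative controls). The B-cell list had 57 up and 94 down of 402 (median -0.04, adjusted p = 0.0488; the median turns to 0.08 with that scaling). The promoter factor list (145 up, 45 down of 496, median 0.15, adjusted p = 0.00127), the keratinocyte list (73 up, 31 down of 245, median 0.18, adjusted p = 0.0221) and the intestinal list, here KLF5 alone (62 up, 22 down of 226, median 0.09, adjusted p = 0.0351), had more members higher. Their calls ended with an estimated correlation (adjusted p = 0.0747, 0.0905 and 0.118). SNAI2, the only member of the insulator and repressor list, had 11 up and 3 down of 44 (median 0.12, adjusted p = 0.0876). Adjusted over the list alone, the counts were 65 up and 27 down for AP-1, 79 and 35 for keratinocyte, 10 and 67 for melanocyte, 9 and 49 for STAT, 146 and 46 for promoter factors, and otherwise the same. With an offset for GC content only the melanocyte list (adjusted p = 0.0197) and AP-1 (adjusted p = 0.000585) passed.

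**Figure D1:**
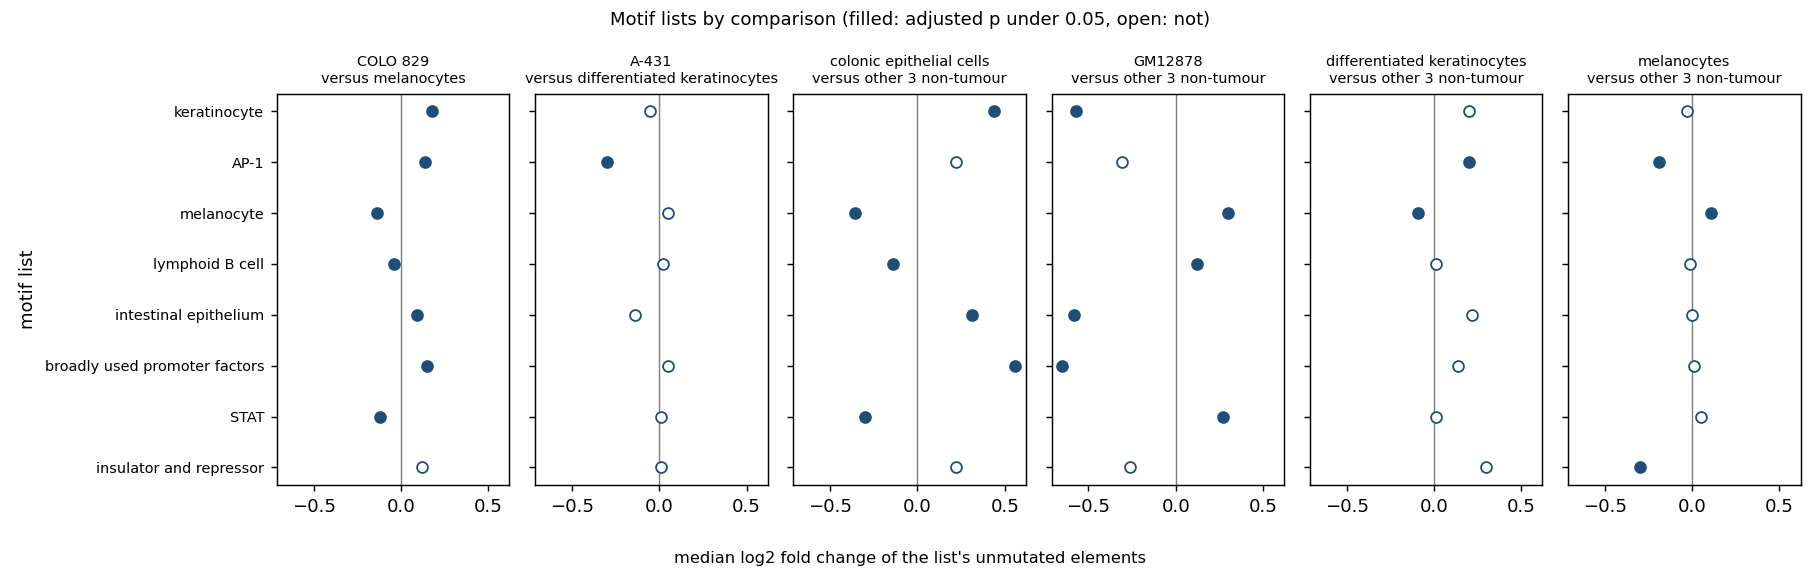
Median log2 fold change of unmutated elements on each of 8 motif lists (vertical axis) in each of 6 comparisons of cell types. The melanocyte list has a median of -0.14 in COLO 829 against melanocytes and 0.11 in melanocytes against the other non-tumour cell types, and AP-1 has -0.3 in A-431 against keratinocytes; medians of the B-cell list in the COLO 829, colonic and GM12878 comparisons and of the keratinocyte list in A-431 change sign with scaling to the negative controls.

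Squamous carcinoma cells were compared with differentiated keratinocytes. The keratinocytes were labelled with 6 days in 1.2 mM calcium and A-431 carried no such label, so cell type and differentiation differed together. Elements naming AP-1 and related basic zipper factors were lower in A-431: 75 of 169 fell and 9 rose (median -0.3, camera adjusted p = 1.04e-08, adjusted p = 0.000385 with an estimated correlation). FOS and JUN factors, whose dimers drive stress and differentiation genes in epidermis, are a part of its 11 names. Among them, medians were -0.43 for FOS, named only with RORA (0 higher, 5 lower of 10), -0.43 for FOSL2 (0 and 11 of 20), -0.39 for JUN (2 and 15 of 30) and -0.32 for JUNB (0 and 11 of 20). Values for the other names (JUND, BATF, BACH1 and the MAF factors) are not given here. Elements naming TP63, the p53 relative that maintains stratified epithelium, had a median of -0.26 (2 higher, 17 lower of 66), but the keratinocyte list that holds it did not pass, and its members KLF4 (0.05), TFAP2B (0.03) and TFAP2C (0.08) had medians above 0. The highest pairs were KLF5::NFYB (median 0.62, 7 of 9 higher) and SP2::TFAP2B (0.52, 7 higher and 0 lower), and the lowest were MAFF::RORA (-0.57, 4 lower), JUN::RORA (-0.52, 6 lower, 1 higher) and EGR2::FOSL2 (-0.51, 6 lower). HBP1::IRF8+GM12878+9+A_scrB rose from 521 ± 9.93 CPM (SD, n = 3) to 2220 ± 15.2 (n = 2), a log2 fold change of 2.09 ± 0.08 SE (edgeR adjusted p = 3.61e-15). KLF4::SREBF2+GDSD6+3+A_scrB fell from 51.9 ± 1.35 to 10.7 ± 3.08 (-2.24 ± 0.23, edgeR adjusted p = 4.5e-08).

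Here 2484 of 9258 elements differed by edgeR, 1163 higher and 1321 lower, and 34 by more than 2-fold (8 higher, 26 lower). Scaled to the negative controls the split was 1792 higher and 842 lower, and the median of all elements moved from -0.01 to 0.1. Without A-431 replicate 1, which leaves 1 sample, 1506 differed. AP-1 was the only list of 8 to pass; adjusted over the list alone 11 were up and 86 down. The others did not: keratinocyte 38 up and 42 down (median -0.05, 0.05 when scaled to the negative controls; adjusted p = 0.988), melanocyte 26 and 22 (0.05, adjusted p = 0.325), B-cell 57 and 56 (0.02, adjusted p = 0.436), intestinal 38 and 53 (-0.14, adjusted p = 0.694), promoter 102 and 60 (0.05, adjusted p = 0.0515), STAT 17 and 24 (0.01, adjusted p = 0.694) and SNAI2 5 and 5 (0.01, adjusted p = 0.96). With DESeq2 size factors 2 lists passed.

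Colonic epithelial cells were compared with the mean of the other 3 non-tumour cell types. Elements on the list of broadly used promoter factors were higher (297 up, 56 down of 496, median 0.56, camera adjusted p = 4.99e-09), as were those on the keratinocyte list (134 up, 39 down of 245, median 0.44, adjusted p = 0.00031). With an estimated correlation the camera adjusted p was 0.00676 for the promoter list and 0.0207 for the keratinocyte list. Of the promoter list, SP1 and SP3, which bind GC boxes of many promoters, had medians of 0.68 (160 higher, 16 lower) and 0.76 (52 and 5), while E2F3, named only with TP63 (-0.1), and ETS1 (-0.12) lay below 0. Of the keratinocyte list, KLF4, a zinc finger factor of epithelial differentiation, had 0.89 (72 higher, 7 lower of 89) and TP63 -0.11. The pair KLF5::NFYB had a median of 1.35 with 8 of 9 elements higher, KLF4::SP3 1.45 (6 higher, 1 lower of 7) and KLF5::MAFK 1.23 (9 higher, 0 lower). Elements naming LEF1 (median -0.44, 2 higher, 43 lower) and SOX10 (-0.38, 7 and 62) were lower, and TFE3 on the same melanocyte list had 0.5 (7 and 0). SP1::TCF3+SCC+10+scrA_scrB, with both motifs scrambled, had 728 ± 4.24 CPM against 182 ± 45.1 (SD, n = 3 and 9; log2 fold change 2.03 ± 0.06 SE, edgeR adjusted p = 2.48e-19), and ETS1::IRF4+GM12878+8+A_B had 22.8 ± 0.455 against 55 ± 14.4 (-1.23 ± 0.10, edgeR adjusted p = 3.11e-11). The median GC content of the unmutated elements was 71.1% for the promoter list, 69.6% for the keratinocyte list and 43.7% for the melanocyte and STAT lists, against 59.3% for all of them.

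By edgeR 6125 of 9258 elements differed, 3048 higher and 3077 lower, and 422 by more than 2-fold, of which 418 were higher. Scaled to the negative controls the split was 3848 higher and 1147 lower, and the median of all elements moved from -0.07 to 0.17. Against each of the other 3 cell types apart, 1500 were higher and 851 lower. The other lists that passed (camera) were intestinal (121 up, 51 down, median 0.31, adjusted p = 0.0034; adjusted p = 0.0561 with an estimated correlation), melanocyte (23 and 112, -0.36, adjusted p = 1.55e-09), STAT (20 and 91, -0.3, adjusted p = 1.7e-06) and B-cell (122 and 149, -0.14, adjusted p = 0.0279; the median is 0.1 with scaling to the negative controls). AP-1 (84 and 38, 0.22, adjusted p = 0.0707) and SNAI2 (18 and 6, 0.22, adjusted p = 0.158) did not. Adjusted over the list alone, 85 AP-1 elements were up, 24 melanocyte elements were up and 114 down, 52 intestinal elements were down and 298 promoter elements were up, and the rest stayed at these numbers. With the GC offset the keratinocyte (adjusted p = 0.403), B-cell (adjusted p = 0.403) and STAT (adjusted p = 0.356) calls ended. The promoter list still passed, with its median down to 0.18 (camera adjusted p = 0.0384), as did intestinal (0.2, adjusted p = 0.0384) and melanocyte (-0.13, adjusted p = 0.00569). AP-1 passed only with that offset (0.21, camera adjusted p = 0.00569).

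GM12878 had lower activity of elements on the promoter factor list than the other 3 non-tumour cell types (81 up, 291 down, median -0.65, camera adjusted p = 1.33e-05) and of elements on the keratinocyte list (45 and 134, -0.57, adjusted p = 0.00139). With an estimated correlation the camera adjusted p was 0.0219 for the promoter list and 0.0342 for the keratinocyte list. Each of the 4 non-tumour cell types was set against the mean of the others, so the 4 values of an element sum to about 0 by construction, and signs in GM12878 and colonic epithelial cells are not independent. Elements naming KLF4 had a median of -1.08 (4 higher, 71 lower of 89), SP1 -0.82 (20 and 151), SP3 -1.11 (5 and 52), and NRF1, a regulator of housekeeping and mitochondrial genes, -1.38 (1 and 8 of 10), all of them in the pair NRF1::SP1, while E2F3 (0.4) and ETS1 (0.17) of the promoter list lay above 0. Members of the B-cell list went both ways: IRF8, an interferon regulatory factor of B and myeloid cells, had a median of 0.28 (77 higher, 32 lower of 139), IKZF1 -0.04 (36 and 44), PAX5 -0.09 (5 and 11), RUNX3, named only with KLF5, -0.28 (1 and 4) and SPIB, named only with IRF8, -0.32 (3 and 5). Pairs with IRF8 among the highest were ETV5::IRF8 (0.68, 8 higher, 1 lower) and CBFB::IRF8 (0.6, 7 higher of 9). Elements on the melanocyte list were also higher (98 of 179, 43 lower, median 0.3, camera adjusted p = 3.79e-05), carried by SOX10 (0.39, 57 and 13) and LEF1 (0.38, 39 and 9), while MITF (-0.98, 2 and 13) and TFE3 (-1.5, 0 and 8) were lower, the latter in elements that all name KLF4 as well. IKZF1::MYBL2+GM12878+7+scrA_scrB had 60.1 ± 2.14 CPM against 16.7 ± 3.18 (SD, n = 3 and 9; 1.84 ± 0.13 SE, edgeR adjusted p = 5.29e-12), and KLF15::OTX1+Colon+9+A_scrB had 10.6 ± 2.97 against 86.7 ± 21.9 (-3.03 ± 0.15, edgeR adjusted p = 3.83e-15).

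By edgeR 6539 of 9258 elements differed, 3258 higher and 3281 lower. By more than 2-fold 1078 differed, 39 higher and 1039 lower. With an offset for GC content 508 differed by more than 2-fold, 400 of them lower. Scaled to the negative controls 1907 were higher and 3941 lower, and the median of all elements moved from 0.03 to -0.18. Lists that passed (camera) were melanocyte, STAT (78 up, 32 down, median 0.27, adjusted p = 0.000219), promoter factors, keratinocyte, intestinal (40 and 130, -0.58, adjusted p = 0.00139) and B-cell (159 and 133, 0.12, adjusted p = 0.0208; -0.1 with scaling to the negative controls). AP-1 (37 and 86, -0.31, adjusted p = 0.124) and SNAI2 (12 and 22, -0.26, adjusted p = 0.802) did not. Adjusted over the list alone, 79 STAT, 160 B-cell and 38 AP-1 elements were up, 41 intestinal were up and 133 down, and 82 promoter elements were up and 292 down. With an offset for GC content 0 of the 6 list calls were left (camera, adjusted p from 0.0552).

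Differentiated keratinocytes had higher activity of AP-1 elements than the other 3 non-tumour cell types: 74 of 169 rose and 14 fell (median 0.2, camera adjusted p = 0.0183, adjusted p = 0.0352 with an estimated correlation). This call ended over all versions of each sequence, where 0 lists passed as higher and 1 as lower. JUN elements had a median of 0.34 (15 higher, 1 lower), JUNB 0.35 (10 higher, 0 lower), KLF4 0.32 (50 and 4) and TP63 0.2 (25 and 4). SOX10 elements were lower (-0.15, 7 and 36), although MITF (0.4, 11 and 3) and TFE3 (0.43, 7 and 0) on the same melanocyte list were higher. EGR2::KLF4 (0.7, 5 of 8 higher) and ID4::TP63 (0.64, 5 of 9 higher) were the highest pairs named, and FOXM1::SOX13 (-0.34, 2 higher, 7 lower) the lowest. EGR2::FOSL2+GDSD6+10+A_B had 148 ± 11.5 CPM against 39.9 ± 19.5 (SD, n = 3 and 9; 2.04 ± 0.10 SE, edgeR adjusted p = 9.29e-15), and KLF15::ZNF589+Melanocytes+5+scrA_scrB 4.74 ± 0.616 against 15.3 ± 3.19 (-1.65 ± 0.19, edgeR adjusted p = 1.59e-07). By edgeR 4166 elements differed, 2382 higher and 1784 lower, and 70 by more than 2-fold (66 higher). The melanocyte list was the other to pass (37 up, 60 down, median -0.09, adjusted p = 0.000829).

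The remaining lists in keratinocytes did not pass in camera. These were keratinocyte (97 up, 22 down, median 0.2, adjusted p = 0.0545), intestinal (100 and 30, 0.22, adjusted p = 0.0545), promoter (173 and 63, 0.14, adjusted p = 0.292) and SNAI2 (17 and 6, 0.3, adjusted p = 0.129). The B-cell list (116 and 64, 0.01, adjusted p = 0.662) and STAT (34 and 33, 0.01, adjusted p = 0.139) had medians above 0 and a test statistic below 0. Adjusted over the list alone, 99 keratinocyte elements were up and 23 down, 61 melanocyte elements were down, 63 B-cell elements were down, 174 promoter elements were up and 7 SNAI2 elements were down. In place of 2 lists, 4 passed with at least 200 plasmid reads, without colonic epithelial cells replicate 1, or without melanocytes replicate 3.

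Melanocytes had higher activity of elements on the melanocyte list than the other 3 non-tumour cell types, with 68 of 179 higher and 13 lower (median 0.11, camera adjusted p = 7.81e-06, adjusted p = 0.000165 with an estimated correlation). Medians by name were above 0 for each of its members: LEF1, an effector of Wnt signalling, 0.13 (24 and 3), SOX10 0.08 (30 and 6), MITF 0.17 (9 and 3) and TFE3 0.33 (5 and 1). AP-1 elements were lower (28 higher, 67 lower, median -0.19, adjusted p = 0.000316), with JUN at -0.26 (2 and 15). Elements naming SNAI2, a repressor of epithelial genes, were lower (2 higher, 19 lower of 44, median -0.3, adjusted p = 8.86e-05). BACH1::KLF5+GDSD6+10+A_B had 447 ± 34.4 CPM against 56.5 ± 12.2 (SD, n = 3 and 9; 3.01 ± 0.09 SE, edgeR adjusted p = 1.32e-18), and NFE2L1::NR3C1+MM+8+A_B 301 ± 59.5 against 60.2 ± 11.6 (2.35 ± 0.08, edgeR adjusted p = 9.87e-18). PAX5::ZNF589+GM12878+4+A_B was lower, 38.7 ± 4.31 against 186 ± 116 (-1.94 ± 0.10, edgeR adjusted p = 2.5e-14). The SD over 9 libraries spans 3 cell types. By edgeR 3249 elements differed, 1766 higher and 1483 lower, and 130 by more than 2-fold (71 and 59). All 3 list calls passed with the GC offset.

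The lists without a call in melanocytes were keratinocyte (38 up, 59 down, median -0.03, camera adjusted p = 0.294), B-cell (72 and 74, -0.01, adjusted p = 0.828) and STAT (33 and 19, 0.05, adjusted p = 0.254). Intestinal (41 and 51, median 0, adjusted p = 0.463) and promoter factors (87 and 92, median 0.01, adjusted p = 0.828) had test statistics below 0. Adjusted over the list alone, 69 melanocyte elements were up, 30 AP-1 elements were up and 77 down, 22 SNAI2 elements were down, 60 keratinocyte elements were down, 34 STAT elements were up, 88 promoter elements were up and 44 intestinal elements were up. In the comparisons of each non-tumour cell type with the others, regroupings that mix libraries of several cell types also gave up to 8 list calls, so the number of calls per comparison does not set the real grouping apart.

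Elements were also grouped by the tags under which the study chose its pairs, which are not independent evidence of direction. The GM12878 tag was higher in GM12878 (161 up, 124 down, median 0.14, camera adjusted p = 0.015), and so was the MM tag (212 up, 91 down, median 0.27, adjusted p = 2.36e-07). The Colon tag in colonic epithelial cells (0.06, adjusted p = 0.399), the Melanocytes tag in melanocytes (0.04, adjusted p = 0.26) and the SCC tag in A-431 (0.03, adjusted p = 0.411) did not pass. The GDSD6 tag was higher in keratinocytes (0.22, 202 up and 52 down, adjusted p = 0.00124) and in COLO 829 against melanocytes (0.11, adjusted p = 0.00515), and lower in A-431 against keratinocytes (-0.21, adjusted p = 0.00134) and in melanocytes (-0.12, adjusted p = 0.000339). The GM12878 tag was lower in colonic epithelial cells (-0.16, adjusted p = 0.0157) and COLO 829 (-0.06, adjusted p = 0.04). The MM tag, with the lowest median GC content (44.4%), was lower in colonic epithelial cells (-0.32, adjusted p = 7.3e-12), keratinocytes (-0.08, adjusted p = 0.000225) and COLO 829 against melanocytes (-0.12, adjusted p = 1.24e-05), and higher in melanocytes (0.08, adjusted p = 0.000339). The SCC tag, with the highest (73.3%), was higher in colonic epithelial cells (0.67, adjusted p = 1.19e-09) and COLO 829 (0.18, adjusted p = 0.000546; adjusted p = 0.0523 with an estimated correlation) and lower in GM12878 (-0.8, adjusted p = 2.36e-07).

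Fold changes between cell types were compared between copies of a sequence. Over 369 pairs of the same sequence with separate barcodes, log2 fold changes correlated at 0.91 for colonic epithelial cells, 0.85 for GM12878, 0.74 for melanocytes, 0.64 for keratinocytes and for COLO 829 against melanocytes, and 0.54 for A-431 against keratinocytes (Pearson, across pairs of elements, which are not replicates). Of the calls in the first copy, 55.3% were also called in the second in A-431, 60.4% in COLO 829, 65.6% in melanocytes, 72.2% in keratinocytes, 84.1% in GM12878 and 89.7% in colonic epithelial cells. Where both copies were called, they had the same direction in 91.9% (keratinocytes) to 99.2% (colonic epithelial cells) of pairs.

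Scrambling both motifs lowered activity on average. Over 1765 distinct sequences the mean log2 change was -0.33 in colonic epithelial cells (95% interval -0.38 to -0.29), -0.33 in keratinocytes (-0.37 to -0.29), -0.3 in A-431 (-0.34 to -0.26), -0.29 in COLO 829 (-0.33 to -0.24), -0.24 in melanocytes (-0.28 to -0.21) and -0.09 in GM12878 (-0.12 to -0.06). Each had a two-sided sign-flip permutation p = 1e-05, the smallest that 100000 resamples give. JUNB::RORA+GDSD6+7 in COLO 829 had a log2 RNA over plasmid of 4.25 unmutated, 2.1 with the left and 0.92 with the right motif scrambled, and -1.01 with both (over barcodes -4.39 for both). Its right stretch, GGCAGCATTGAGTCAGCAAGG, held an AP-1 site. BACH1::KLF5+GDSD6+10 in melanocytes went from 4.45 to 0.36 (left), 0.58 (right) and -1.16 (both; -5.55 over barcodes, limma adjusted p = 8.07e-11). PRDM1::RORA+GDSD6+9 in keratinocytes was at 1.67 unmutated, 2.8 with the left and -1.77 with the right motif scrambled. EBF1::SP4+GM12878+6 in colonic epithelial cells rose instead, from -0.45 to 4.18 with both scrambled (3.96 over barcodes, limma adjusted p = 1.1e-07).

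**Figure D2:**
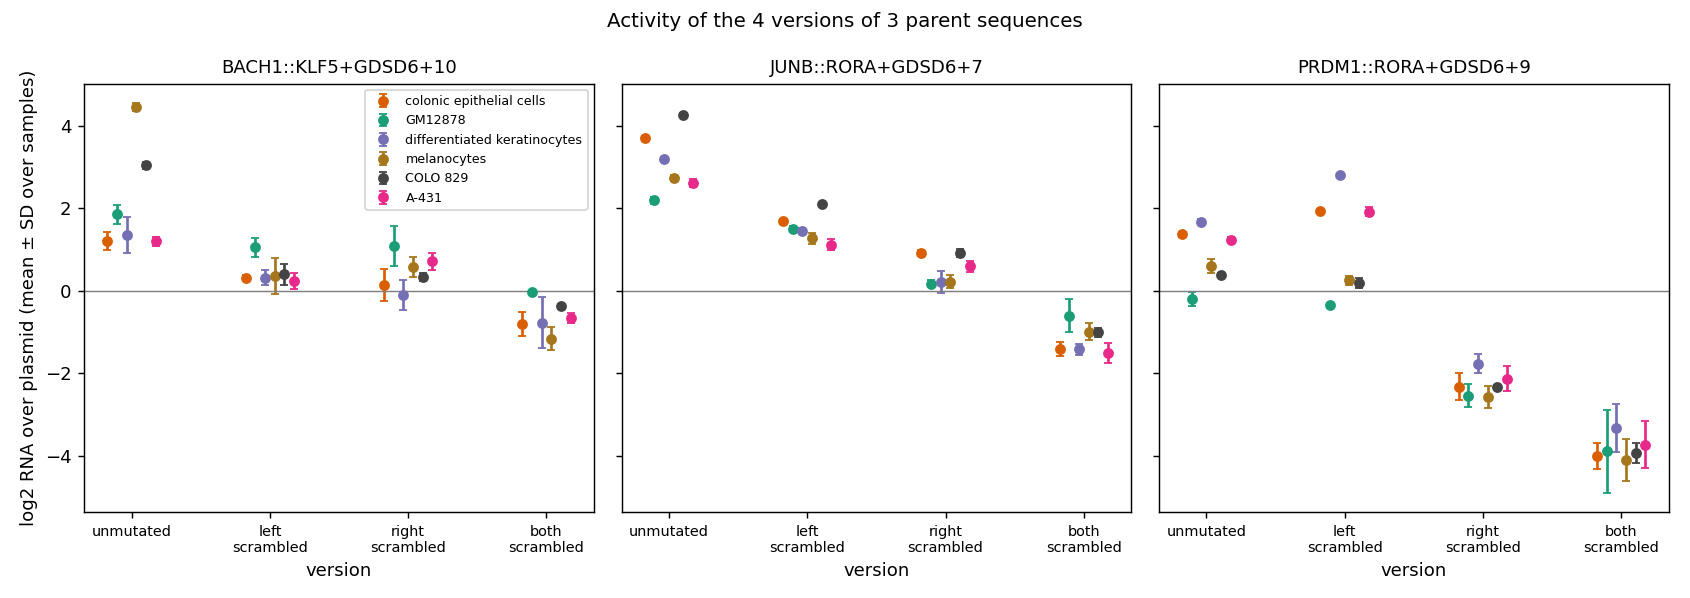
Log2 RNA over plasmid (vertical axis, mean ± SD over libraries) of the 4 versions of BACH1::KLF5+GDSD6+10, JUNB::RORA+GDSD6+7 and PRDM1::RORA+GDSD6+9 in 6 cell types. Unmutated BACH1::KLF5+GDSD6+10 is at 4.45 in melanocytes and 3.04 in COLO 829 against 1.21 in colonic epithelial cells and 1.85 in GM12878.

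The number of sequences changed depended on what was taken as the replicate. The planned edgeR test over libraries called 1835 of 2223 sequences in colonic epithelial cells (642 higher, 1193 lower), 1554 of 2221 in keratinocytes (495, 1059), 1629 of 2223 in melanocytes (586, 1043), 1896 of 2227 in COLO 829 (697, 1199), 1660 of 2225 in A-431 (554, 1106) and 1247 of 2207 in GM12878 (521, 726). The same test called 53.9% (GM12878) to 79.5% (COLO 829) of pairs of one unmutated sequence with separate barcodes, which have no sequence difference. The limma test over barcodes called 275, 246, 202, 309, 204 and 46 of 2180 sequences in that order, of which 225, 207, 154, 249, 167 and 27 were lower, and 1, 1, 0, 0, 0 and 0 of 364 pairs of one sequence; 3.57% to 6.04% of these pairs had an unadjusted p under 0.05. In simulations that test recovered 17 of 200 changes of 2-fold, so smaller effects of single sequences were mostly not detectable.

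**Figure D3:**
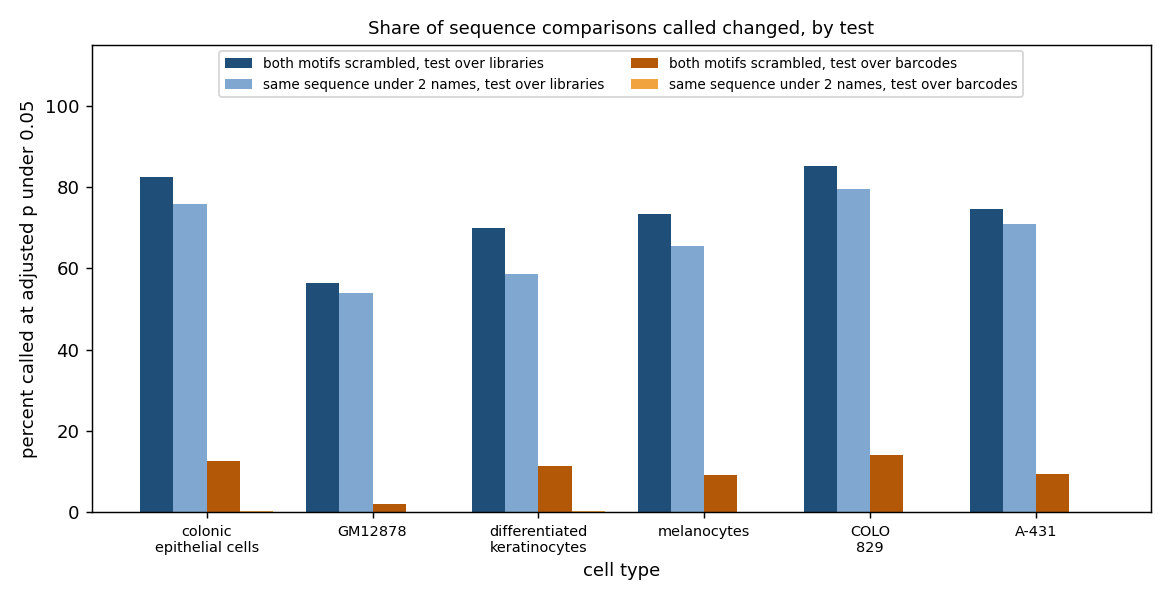
Percent called changed (vertical axis, from 0) per cell type for sequences with both motifs scrambled and for pairs of one unmutated sequence with separate barcodes, with libraries or barcodes as replicates. Over libraries 53.9% to 79.5% of the same-sequence pairs are called, and over barcodes at most 0.275%.

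Departure from additivity, the question of whether a pair of motifs does more or less than the sum of both on the log2 scale, was not resolved for single sequences. The planned edgeR test over libraries called 1662 sequences in colonic epithelial cells, 1369 in keratinocytes, 1454 in melanocytes, 1782 in COLO 829, 1431 in A-431 and 1092 in GM12878, with medians from -0.01 to 0.02. The limma test over barcodes called 4 in COLO 829 and 0 in the others, with 177, 183, 166, 193, 171 and 136 at an unadjusted p under 0.05 in that order of cell types. The 4 were IRF4::SP4+GM12878+2 (3.7), ID4::TP63+GDSD6+6 (5.06), KLF15::SNAI2+Colon+3 (-3.5) and EBF1::ZNF816+GM12878+5 (-3.44), listed because they were the only calls. In simulations 120 of 200 departures of 4-fold were recovered. Of 239 pairs, 0 passed in any cell type in an exact sign-flip test (1434 tests), for both motifs scrambled (16 to 39 at an unadjusted p under 0.05) or for departure from additivity (6 to 13). With at most 10 sequences per pair the exact p cannot fall below 0.00195, so a pair could hardly pass over 1434 tests and the count of 0 says little. The lowest mean in colonic epithelial cells was that of KLF4::SP1, -2.2 ± 0.62 SE with 6 of 6 sequences lower (exact p = 0.0312, adjusted p = 0.342).

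Activity was lower on average after loss of 5 of 14 known sites tested. The whole stretch around a site was scrambled, and stretches that also held or gained another listed site were not left out. The fall may therefore not belong to the named site alone. Where a scrambled stretch lost a GC box, the site of SP and KLF factors, mean activity fell by 0.52 ± 0.07 (SE) on the log2 scale in colonic epithelial cells, 0.14 ± 0.05 in GM12878 (permutation adjusted p = 0.0162), and by values between these in the other cell types (235 sequences, adjusted p = 9.33e-05 each). Loss of an ETS site gave -1.3 ± 0.27 in keratinocytes, with 18 of 18 sequences lower (permutation adjusted p = 0.000153), and -1.34 ± 0.29 in colonic epithelial cells (permutation adjusted p = 0.00147). Loss of an E-box, the site of helix-loop-helix factors, gave -0.89 ± 0.2 in melanocytes (34 of 41 lower, permutation adjusted p = 0.000153) and -0.91 ± 0.19 in keratinocytes (permutation adjusted p = 0.000194). It also passed in COLO 829 (-0.79), colonic epithelial cells (-0.63) and A-431 (-0.54), and not in GM12878 (-0.17, permutation adjusted p = 0.449). Loss of an AP-1 site gave -0.58 ± 0.13 in colonic epithelial cells (50 of 71 lower, permutation adjusted p = 0.0003), -0.45 ± 0.12 in keratinocytes (permutation adjusted p = 0.00158) and -0.44 ± 0.12 in COLO 829 (permutation adjusted p = 0.0038). It did not pass in melanocytes (-0.19, permutation adjusted p = 0.27), A-431 (-0.19, adjusted p = 0.273) or GM12878 (-0.02, adjusted p = 0.91). CACCC boxes passed in all cell types but GM12878 (-0.11, permutation adjusted p = 0.146), with -0.46 ± 0.08 in keratinocytes.

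**Figure D4:**
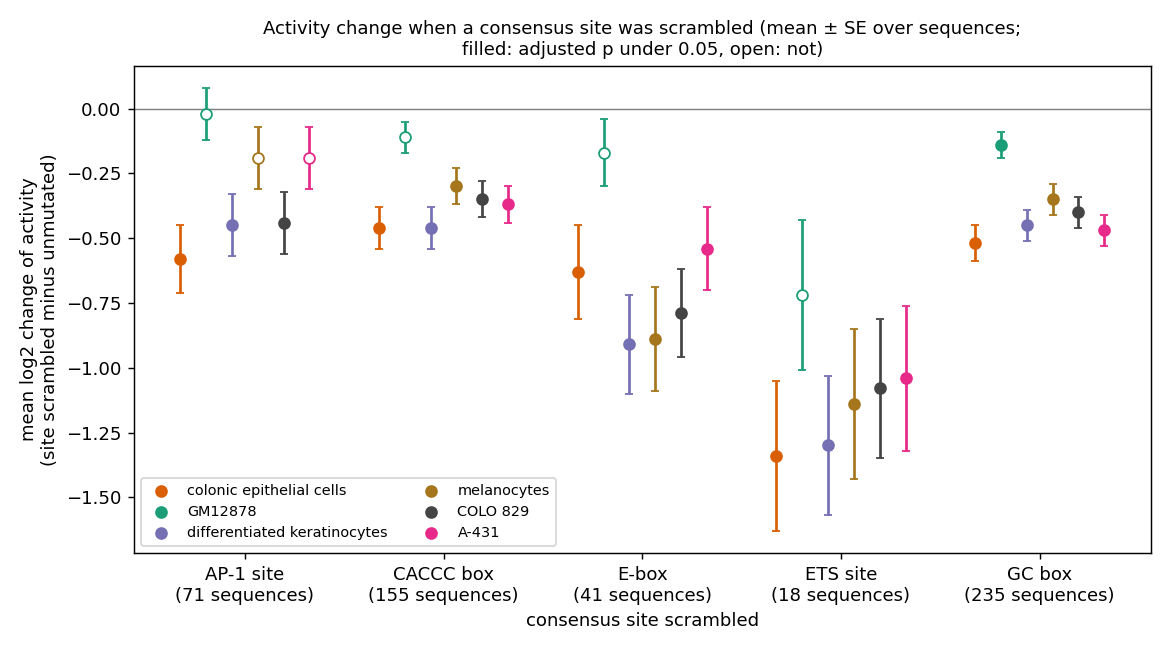
Mean log2 change (vertical axis, ± SE over sequences) after scrambling a stretch that held an AP-1 site, CACCC box, E-box, ETS site or GC box, in 6 cell types; filled points passed at an adjusted p under 0.05. Loss of the GC box is at -0.52 in colonic epithelial cells and -0.14 in GM12878.

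In all, 5 of 14 sites tested passed in colonic epithelial cells, keratinocytes and COLO 829, 4 in melanocytes and A-431, and 1 in GM12878, all lower. These tests are against 0. Against 2601 stretches with none of the listed sites, whose means ran from -0.14 to -0.04, the GC box in GM12878 did not pass (permutation adjusted p = 0.196), the ETS site there did (-0.69, adjusted p = 0.0034), and the other calls were the same. The call for scrambling the GC box in GM12878 ended without GM12878 replicate 2 (permutation adjusted p = 0.0756). Sites of AP-2, CCAAT, EGR, LEF, SOX, STAT, forkhead and nuclear receptor factors and the paired GAAA repeat passed in no cell type. Of sequences grouped by motif name, with both motifs scrambled, 23 of 123 names passed in colonic epithelial cells, 22 in keratinocytes, 20 in A-431, 18 in melanocytes, 18 in COLO 829 and 6 in GM12878, again all lower (permutation, 738 tests). Sequences naming KLF4 fell by 0.95 in colonic epithelial cells and 0.24 in GM12878 (permutation adjusted p = 0.0463). Those naming MITF had means of -1.03 in melanocytes and -1.09 in keratinocytes. Of these names SOX10 passed in melanocytes and in no other cell type (-0.33 ± 0.1, permutation adjusted p = 0.0212). The name tests too are against 0, and over 1765 distinct sequences the mean in melanocytes was -0.24 (over barcodes). Passing by itself therefore does not set sequences naming SOX10 apart from the others. With at least 200 plasmid reads, scrambling both motifs of sequences naming SOX10 in melanocytes no longer passed (-0.26, permutation adjusted p = 0.0769). A mean over sequences naming a motif belongs to the pairs that name it, since both stretches were scrambled. The name and site tests were chosen after the data were seen.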

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

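The tests of single sites and motif names and both tests of barcode sets were chosen only after the result was seen. So were the test of plasmid carry-over and the GC tests of the GM12878 and melanocyte lists. The tests of depth, of scrambled motifs on the GC trend and of other splits were fixed before their result was seen. So was the test of GC content on elements changed by more than 2-fold, although its GC offset was added after the data were seen. Groups of 3 libraries were not tested for a sample far from the others. Over elements, the chi-square per degree of freedom, which rises with depth, was 8.28 and 6.73 for COLO 829 replicate 2 against replicates 1 and 3 and 1.27 between those, and for melanocytes it was 12.1 between replicates 2 and 3 against 3.52 and 5.18 for the other pairs.

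The effect of losing an AP-1 site differed from the mean of the other 5 cell types in each of the 6, which is why it is listed: the difference was -0.33 in colonic epithelial cells (permutation adjusted p = 0.000168), -0.17 in keratinocytes (0.00199), -0.15 in COLO 829 (0.0063), 0.14 in A-431 (0.0063), 0.15 in melanocytes (0.00946) and 0.35 in GM12878 (0.000168). These 6 values sum to 0 by construction and are not independent of one another. The other differences below were tested in the same way. The GC box differed by -0.16 in colonic epithelial cells, -0.08 in keratinocytes, -0.1 in A-431 and 0.29 in GM12878. The CACCC box differed by -0.14 in colonic epithelial cells, -0.14 in keratinocytes and 0.28 in GM12878. The E-box differed by -0.3 in keratinocytes, -0.28 in melanocytes and 0.58 in GM12878, and the ETS site by -0.28 in colonic epithelial cells. The LEF site differed by -0.19 in melanocytes and -0.14 in COLO 829, the SOX site by -0.1 in melanocytes, and the forkhead site by -0.3 in A-431 and 0.2 in COLO 829, although the effects of these 3 sites did not pass in any cell type by themselves (LEF in melanocytes -0.11, permutation adjusted p = 0.564). Each of the 4 differences in melanocytes ended under an alternative: those of AP-1, E-box and SOX without melanocytes replicate 3, and those of LEF and SOX over barcodes. In the other cell types those of AP-1 and E-box in keratinocytes, ETS in colonic epithelial cells and forkhead in COLO 829 ended under at least 1 alternative.

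Sequences grouped by motif name also differed between cell types when both motifs were scrambled. In GM12878 the difference from the other 5 was 0.81 for JUNB, 0.85 for OTX1, 0.55 for KLF4, 0.55 for ZNF219, 0.45 for SREBF2, 0.38 for KLF5, 0.38 for SP1, 0.37 for SP3, 0.36 for JUN, 0.3 for EGR2, 0.28 for KLF15 and 0.21 for NFE2L1. In colonic epithelial cells it was -0.48 for JUNB, -0.43 for JUN, -0.39 for ZNF219, -0.3 for KLF4, -0.2 for SP3, -0.18 for FOXM1, -0.17 for KLF5, -0.17 for KLF15, -0.17 for SP1 and -0.14 for RORA. In keratinocytes it was -0.35 for JUNB, -0.3 for JUN, -0.27 for SNAI2, -0.26 for TP63, -0.2 for EGR2, -0.18 for SP3, -0.17 for KLF15, -0.15 for KLF5 and -0.12 for SP1. In melanocytes it was 0.35 for JUN (permutation adjusted p = 0.00134) and -0.17 for SOX10 (0.00738), in COLO 829 0.29 for SNAI2 (0.0327), and in A-431 -0.14 for SP1 (0.00478) and -0.12 for THAP1 (0.0355). The difference of SNAI2 in COLO 829 ended in 3 of 6 alternatives, that of SP1 in A-431 in 1 of 3 (without the top barcode) and that of THAP1 in 3 of 3. Of the others, 8 of 9 in keratinocytes, 5 of 10 in colonic epithelial cells, 3 of 12 in GM12878 and 0 of 2 in melanocytes ended under at least 1 alternative. Leaving out a library ended JUN in GM12878 (replicate 2), JUNB and SP3 (replicate 2) and RORA (replicate 3) in colonic epithelial cells, and in keratinocytes JUNB (replicate 1 or 3), KLF15 (2), SNAI2 (any), SP1 (3), SP3 (1) and TP63 (3). The overall mean after scrambling also differed, from -0.09 in GM12878 to -0.33 in colonic epithelial cells and keratinocytes, so a difference of a name is in part that of all sequences.

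The first pattern is the large number of sequences called changed after scrambling. Barcode sets may give such calls with no sequence effect, since over libraries at least 53.9% of pairs of one sequence with separate barcodes were called. They do not account for the lower mean, since barcode sets should go either way and the largest sign-flip permutation p over the cell types was 1e-05, the smallest these resamples can give. How many of the single sequences called over libraries carry an effect of their own stays open.

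The second pattern is that GM12878 stood apart. Plasmid-derived reads are argued against: the 85 elements least active in the other 3 non-tumour cell types had 13.4% of their plasmid level in GM12878 (13.3% to 13.5% over libraries), which limits the share of such reads and what they take from any element, while the 1039 elements lower by more than 2-fold were at 54.2% of the other cell types or less. Depth is argued against by thinning the libraries of the non-tumour cell types to 1958642 reads. The lowest correlation between the other 3 of these cell types was then 0.828, above the highest with GM12878 of 0.792. In the fit, where libraries of the melanoma and carcinoma lines stayed at full depth, 996 elements differed by more than 2-fold. GC content may contribute, since with a GC offset 508 elements differed by more than 2-fold (400 lower) against 1078 without it (1039 lower), and the SD of log2 fold changes went from 0.807 to 0.727, so it is not the whole of it. The scrambled stretches are argued against as the main origin of the GC trend, whose slope with both scrambled was 0.81 of that unmutated (0.74 to 0.88). This interval lies below that of an unchanged slope, so scrambling did lower the trend. Sites outside these stretches, and sites that scrambling may have made, were not tested. A difference between lymphoid and other cells stays open and untested.

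The third pattern is the shift of motif lists. In GM12878, GC content could account for a part of the shifts, since 0 of 6 list calls were left with a GC offset. Medians went from -0.65 to -0.22 for promoter factors, -0.57 to -0.17 for keratinocyte and -0.58 to -0.34 for intestinal. They went from 0.3 to 0.06 for melanocyte, 0.27 to 0.08 for STAT and 0.12 to 0.1 for the B-cell list. In melanocytes GC content is argued against, since 3 of 3 list calls were left. Members of the melanocyte list had medians of 0.08 (SOX10), 0.13 (LEF1), 0.17 (MITF) and 0.33 (TFE3) in melanocytes, beside 0.39 for SOX10 and 0.38 for LEF1 in GM12878 and 0.4 for MITF and 0.43 for TFE3, named only with KLF4, in keratinocytes. A difference between melanocytes and the other cells stays open and untested.

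Other splits of the samples were run for each count. For COLO 829 against melanocytes 1 of 10 splits gave as many elements (3356 against at most 0 in another) and 1 of 10 as many lists (7 against 6), and 10 splits are too few for a share under 0.05. The elements differing in colonic epithelial cells (6125), GM12878 (6539), keratinocytes (4166) and melanocytes (3249) were each reached by 1 of 100 regroupings, the real one, with at most 3097 in another. This excludes that cell type made no difference to any library, but not chance for each cell type by itself, since regroupings mix cell types, which widens the spread within groups and can lower their counts. The margin was smallest for melanocytes, where 2641 differed without melanocytes replicate 1. Chance cannot be excluded for the numbers of lists: 38 of 100 regroupings gave as many as the 6 in colonic epithelial cells, 38 as many as the 6 in GM12878, 74 as many as the 2 in keratinocytes and 65 as many as the 3 in melanocytes, with up to 8 in another. Regroupings that mix cell types can carry list shifts of those cell types, so these shares do not decide the question. With version names swapped in 1 library of 3 there are 4 arrangements, too few for such a share: the real one gave 1835, 1247, 1554, 1629 and 1896 changed sequences and 1662, 1092, 1369, 1454 and 1782 non-additive ones in colonic epithelial cells, GM12878, keratinocytes, melanocytes and COLO 829, and the highest other gave 0.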

How the results depend on the processing

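The GC offset, the test over barcodes, the counting of near-identical replicates and all alternatives for sites and motif names were chosen after the data were seen; the others were planned. Counts of elements, active elements and changed sequences stayed within 1.5 times of the first value under other scalings, filters and count tests, except as follows, and unless stated the cause was not tested. A minimum change of 1 on the log2 scale, which asks for larger effects by construction, left 31 elements in COLO 829 against melanocytes, 34 in A-431 against keratinocytes, 422 in colonic epithelial cells, 1078 in GM12878, 70 in keratinocytes and 130 in melanocytes, and 1418, 618, 1169, 987, 1031 and 1092 active elements in colonic epithelial cells, GM12878, keratinocytes, melanocytes, COLO 829 and A-431. Over barcodes, 275, 46, 246, 202, 309 and 204 sequences changed in that order, and 0, 0, 0, 0, 4 and 0 were non-additive. Motif lists in COLO 829 numbered 4 with an estimated correlation and 2 with a GC offset, in GM12878 0 with a GC offset, in keratinocytes 1 with all versions and 4 with at least 200 plasmid reads, and in A-431 2 with DESeq2 size factors, with no low-count filter and with at least 200 plasmid reads. Sites whose effect differed numbered 2 in melanocytes over barcodes and 5 in A-431 without the top barcode, and sites changed in GM12878 2 with at least 200 plasmid reads and 2 without the top barcode. Motif names whose effect differed numbered 4 in melanocytes over barcodes and 4 with at least 200 plasmid reads, 1 in A-431 over barcodes and 0 without the top barcode, 5 in keratinocytes with at least 200 plasmid reads and 5 without the top barcode, and 0 in COLO 829 with at least 200 plasmid reads.

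Leaving out libraries, elements in A-431 against keratinocytes ranged from 1506 (without A-431 replicate 1) to 2431, lists in keratinocytes from 2 to 4 (without colonic epithelial cells replicate 1 or melanocytes replicate 3), lists in A-431 from 1 to 2 (without keratinocyte replicate 3 or A-431 replicate 3), sites changed in GM12878 from 0 (without GM12878 replicate 2) to 1, sites differing in melanocytes from 1 (without melanocyte replicate 3) to 4, and names differing in keratinocytes from 5 (without keratinocyte replicate 3) to 7. Where 1 sample was left, it was assumed to vary like the other groups. The scrambling of A-431 without replicate 1 was not run. Without the top barcode the direction turned for KLF15::SNAI2+Colon+8+A_B in GM12878 (-0.41, edgeR adjusted p = 0.183), EGR1::IKZF1+GM12878+3+scrA_scrB in melanocytes (-0.14, edgeR adjusted p = 0.842) and the departure from additivity of SNAI2::SP1+SCC+9 in COLO 829 (-0.13, edgeR adjusted p = 0.848), which rested on 1 barcode each. Depth limits GM12878 most, with a median of 78 reads per element in replicate 3.

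Replicate numbers shared between cell types were not used to pair the libraries. The 45 same-numbered pairs had a mean correlation of deviations of 0.004 (-0.159 to 0.08). Of 18 libraries, 11 correlated best with their own number, more than an even draw over the numbers gives, so pairing was not excluded. Between melanocytes and COLO 829, replicates 2 and 3 correlated at 0.176 and 3 and 2 at 0.136. Same-numbered replicates of these groups were at -0.159 (2) and -0.154 (3). With a replicate block the elements differing in COLO 829 versus melanocytes numbered 3299 and the elements differing in A-431 versus differentiated keratinocytes 2331, and 2 lists passed in A-431 in place of 1; no other count of elements, lists or active elements moved by more than 1.5 times.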

Other observations

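The tests of GC content by slope were fixed before their result was seen, and the values on copies of one sequence were chosen after. Some activity differences between cell types moved with GC content both in unmutated sequences and in those with both motifs scrambled, which keep the rest of the element. Over 2247 sequences the difference of GM12878 from the other 3 non-tumour cell types changed by -0.28 on the log2 scale per 10% GC unmutated and by -0.23 with both motifs scrambled, that of colonic epithelial cells by 0.27 and 0.22, and that of COLO 829 from melanocytes by 0.1 and 0.08. The slopes were 0.05 and 0.01 in keratinocytes, -0.04 and 0 in melanocytes and 0.03 and 0.01 in A-431 against keratinocytes, and the intervals of their ratio held 0. Across these sequences, which are not replicates, r for GM12878 was -0.45 unmutated and -0.41 scrambled.

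Some elements that differed most between cell types had 1 or both motifs scrambled. SP3::TFAP2C+SCC+8+scrA_B had 922 ± 26 CPM in colonic epithelial cells against 202 ± 124 in the other 3 non-tumour cell types (SD, n = 3 and 9; edgeR adjusted p = 2.31e-21), and KLF5::MAFG+GDSD6+7+scrA_B had 168 ± 19.6 in GM12878 against 1280 ± 567 (edgeR adjusted p = 2.17e-19). EGR2::FOSL2+GDSD6+10+A_scrB, with the right motif scrambled, had 929 ± 69.2 in keratinocytes against 203 ± 121 (edgeR adjusted p = 5.14e-21), beside 148 ± 11.5 for its unmutated version. These CPM are RNA reads that were not set against plasmid reads. Versions carry different barcodes, so levels of 2 versions also differ by plasmid abundance and barcode set. They do not give the effect of scrambling. Each SD over 9 libraries spans 3 cell types.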
